A study of Mus musculus with 4 samples.

How the data were processed

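Polyadenylated RNA from mouse bone marrow-derived cells grown with Flt3 ligand was sequenced in 4 libraries, 1 each for wild-type (C57) and Nfkb1 knockout cells at day 3 and day 5. Per the labels' protocols, RNA was extracted with trizol and libraries were made with a Kapa mRNA HyperPrep kit. Per the submitters' processing notes, HISAT2, SAMtools and the mm9 genome build were used, without versions. The counting tool, the annotation release and the use of strand are not given in the sources used here. The deposited table holds RPKM values made by the authors, per the file headers, with 1 row for each of 26026 genes, named by RefSeq accession and symbol, and 1 column per library. Columns were assigned to libraries by the genotype and day in their names, and no column was left over.

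No value in the table was 0. The values are whole multiples of the worth of 1 read, which depends on gene length and library total. From these steps the library totals and, for all 26026 genes, whole reads and a gene length were recovered (tolerance 0.003 reads). The smallest length that gave whole reads was taken, and its multiple was set by the reference transcript for 594 genes. A reference length was at hand for 22187 genes, so for the others reads and length may be too small by a whole factor. Genes without reads stand at the value of 1 read, or 1 read was added to every gene; the table does not settle which, and 7985 genes stood at 1 read in all libraries. The recovered totals ran from 15255070 to 16215214 reads, of which 70.5% (wild type, day 3), 75.4% (knockout, day 3), 73.7% (wild type, day 5) and 73.9% (knockout, day 5) fell in the listed genes. The 10 genes with most reads held between 5.14% and 6.91% of them. Intervals of a ratio are exact (Clopper-Pearson) 95% intervals of the recovered reads. They cover counting error only and take each read as an independent molecule. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for that error. Sequencing depth was alike between libraries, so few reads of a gene limit precision within a library, and the single library per group limits every comparison between them.

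Values were analysed as log2(RPKM + 1) without further scaling. Genes with a mean of at least 1 RPKM over the 4 libraries (11786) entered the comparisons. The comparisons were knockout against wild type at each day, day 5 against day 3 in each genotype, and the change of the genotype difference between the days. With 1 library per group each is a value with no test, called by a size rule of at least 1 in absolute log2 difference. The 32 gene lists were each described by the median over measured members and by the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list stands apart below percentile 2.5 or above percentile 97.5, which describes these libraries and is no test across replicates. Lists with fewer than 4 measured members got values only. The lists covered NF-kB subunits, their regulators and inflammatory targets, antioxidant, interferon-stimulated, stem cell, cytokine receptor, class I and class II presentation genes, markers of dendritic, monocyte, neutrophil, B, T and NK, erythroid, mast and basophil, megakaryocyte and stromal cells, and proliferation, cell cycle, survival, Toll-like receptor, energy metabolism, stress, sex-linked, reference, ribosomal and histone genes. An additive limma fit (genotype and day, empirical Bayes, Benjamini-Hochberg adjustment, threshold 0.05) served as support only.

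Named genes follow a rule fixed before the data were examined. It takes Nfkb1, Nfkb2, Rela, Relb, Rel, Sod2 and Flt3, the 10 higher and 10 lower genes past the size rule in the same direction at both days, and likewise in both genotypes, ranked by the smaller absolute difference. It adds the 5 largest rises and 5 largest drops of the genotype difference, and for each list up to 4 members with the largest difference past the rule in a comparison. Predicted genes without a name, receptor segments and sex-linked genes were left out of the ranked parts. Any other gene is said to have been chosen after its values were seen, or is named in a test of an explanation (Ubb, Gapdh, Actb and neighbours of Nfkb1).

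Also fixed beforehand were the lists, the size rule and these alternatives, changed one at a time: pseudocounts of 0.1 and 5 RPKM, no filter, a mean of at least 5 RPKM, rescaling by the median ratio of the libraries, rescaling to the same sum of RPKM, and limma with an intensity trend or robust. A filter of at least 20 recovered reads on average and voom on the recovered reads were added after the data were seen.

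The procedures were tested on simulated libraries drawn from the real gene means and totals with 200 genes changed. The spread between simulated libraries was an assumed value, since 1 library per group gives no estimate of it. The shares of genes found and the false calls given below depend on that choice. All 4 library totals were recovered exactly, and all reads were recovered exactly for 99.7% of 3000 genes. The reference lengths there were those used to simulate, whereas the deposited values were set against GENCODE lengths. That recovery therefore does not measure how exact the recovery from the deposited values was. For knockout against wild type at day 3, the size rule found 20.4% of 49 genes changed by a fold of 2.0, 93.6% of 47 changed by 4.0 and 100% of 46 changed by 8.0, since the pseudocount and a threshold at 2-fold leave out changes of about that size. It also took in 109 of 11829 unchanged genes, but only 4 of 10926 that held at least 20 reads. The additive limma fit found 71.4% of the genes changed by 2.0 and called 74 of 11829 unchanged genes, against 16 of 10926 with at least 20 reads and 12 of 11829 with voom, so its calls among genes of few reads are not reliable. A list raised by 1.5 reached percentile 100, and 1 of the other 30 lists stood apart. Each gene was simulated independently, so that count does not cover real lists whose members move together. Expected counts of genes past the size rule from counting error were means of 20 Poisson draws at the pooled rate of the libraries compared.

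Transcript sequences came from GENCODE M21 and the order of genes from a RefSeq table, both on GRCm38, a build other than that of the deposited values, so no coordinates are given. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.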

Results

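Messenger RNA was profiled in mouse bone marrow-derived cells that were being differentiated with Flt3 ligand, the cytokine that drives dendritic cell development from marrow progenitors. Cells were labelled wild type or knockout for Nfkb1, the gene for the NF-kB subunit p105 and its processed form p50, and were taken at day 3 and day 5 of culture. There was 1 library for each of the 4 combinations of genotype and day, so no difference given here has a replicate check. The library totals recovered from the RPKM values, which are reads scaled to transcript length and library total, were 15255070 reads for wild type at day 3, 16215214 for the knockout at day 3, 16116361 for wild type at day 5 and 15398985 for the knockout at day 5. The questions were how gene expression during this differentiation differed in the Nfkb1 knockout and, from the series title, what happened to Sod2 and to the other NF-kB subunits. Differences are log2 differences of RPKM + 1, which understate the change of low genes. A size rule of at least 1 on that scale was applied to the 11786 genes with a mean of at least 1 RPKM. Intervals are exact 95% intervals of a ratio of reads and cover counting error only.

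Nfkb1 (NM_008689) stood at 74.8 RPKM in wild type and 56.0 RPKM in the knockout at day 3, and at 114 RPKM in wild type and 64.7 RPKM in the knockout at day 5. The ratio of knockout to wild type was 0.749 (0.717 to 0.782) at day 3 and 0.568 (0.547 to 0.590) at day 5. Nfkb1 was thus lower in both libraries labelled knockout but far from absent, and a value summed over the whole gene does not show whether the remaining transcripts carry the disruption. Sod2 (NM_013671), the mitochondrial superoxide dismutase, was higher in the knockout at both days, at 60.7 RPKM against 23.8 RPKM at day 3 and at 55.2 RPKM against 19.96 RPKM at day 5. Its ratio of knockout to wild type was 2.55 (2.40 to 2.71) at day 3 and 2.77 (2.59 to 2.96) at day 5. No subunit gene passed the size rule between genotypes, Nfkb1 included, which differed by -0.41 at day 3 and -0.81 at day 5. Nfkb2, which encodes p100 and p52, differed by -0.29 at day 3 and -0.08 at day 5, Rela by -0.14 and -0.31, Rel by -0.26 and -0.28, and Relb by 0.07 and -0.03. Flt3, the receptor for the ligand in the medium, differed by 0.10 at day 3 and -0.58 at day 5.

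**Figure D1:**
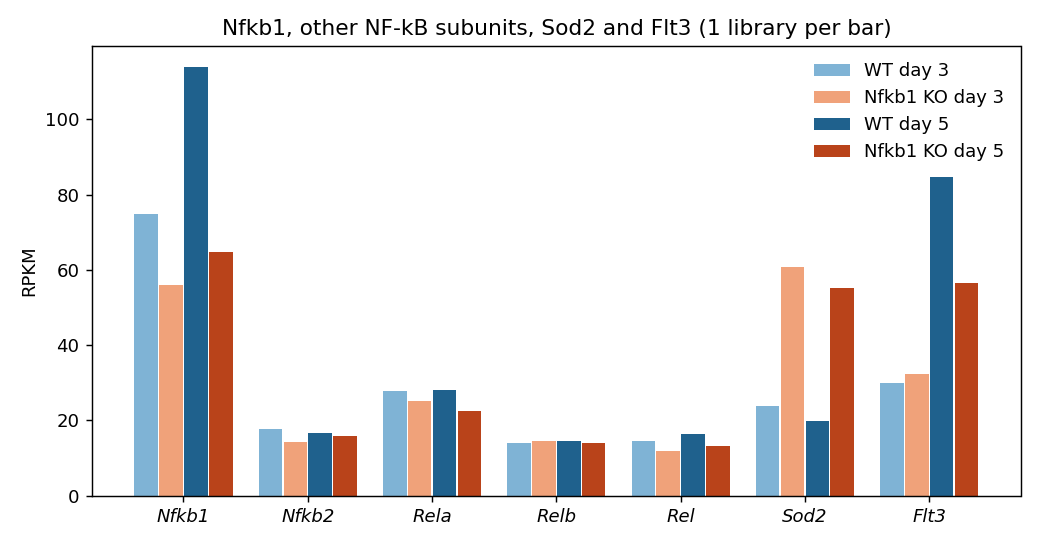
RPKM of Nfkb1, the other NF-kB subunit genes, Sod2 and Flt3, with 1 bar per library (wild type and knockout at day 3 and day 5) and no error bars since each group has 1 library. Sod2 stood at 60.7 and 55.2 RPKM in the knockout libraries against 23.8 and 19.96 RPKM in wild type, and Nfkb1 was lower in the knockout at both days.

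Among the genes higher in the knockout at both days, Saa3, an acute phase serum amyloid, had the largest difference shared by the days. It rose from 33.5 RPKM in wild type to 1002 RPKM in the knockout at day 3, a ratio of 29.9 (26.5 to 33.9), and from 12.7 to 1504 RPKM at day 5, a ratio of 118 (97.8 to 144). Marco, a scavenger receptor of macrophages, was higher by 1.78 at day 3 and 2.95 at day 5, and Cfb, complement factor B, by 1.69 and 3.50. The pattern recognition lectin Clec4e was higher by 1.51 and 2.34 and the receptor Gpr84 by 1.66 and 2.42. Gbgt1 (1.78 and 1.85), Ly6i (1.70 and 1.87), Lox (1.84 and 1.58), Marcksl1 (1.58 and 1.82) and Alpk1 (1.53 and 1.73) completed the 10 with the largest difference shared by the days. Among the genes lower at both days, Gimap3 and Gimap4, GTPases of lymphocytes, differed by -2.12 and -1.66 at day 3 and by -1.99 and -1.48 at day 5. Fcer2a, the low-affinity IgE receptor of B cells, differed by -2.01 and -1.89, Cd3g of the T cell receptor complex by -1.62 and -1.55, H2-Oa by -1.51 and -1.68, and the chemokine Ccl22 by -1.33 and -1.58. Hbb-b1, a beta globin, differed by -2.21 and -1.47, with Hbb-bs at -2.20 and -1.47; these near-identical copies held 1950 and 1944 reads in wild type at day 3 and cannot be counted as separate observations. Mir7670 (15, 2, 18 and 3 reads) and Mir7078 (8, 2, 8 and 2 reads) also ranked there, on too few reads to place their size. For Mir7078 the interval of the ratio included 1 at both days, running from 0.0243 to 1.18 at day 3.

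**Figure D2:**
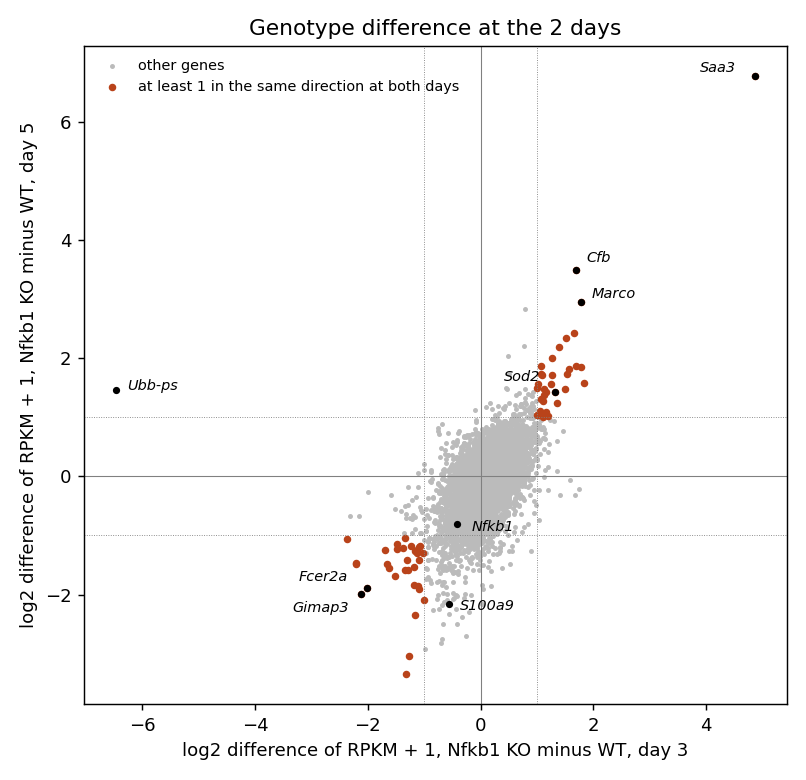
Each point is a gene with at least 20 recovered reads on average, placed by its log2 difference of RPKM + 1 between the knockout and the wild-type library at day 3 (x axis) and at day 5 (y axis), with dotted lines at the size rule of 1. Saa3 lies at 4.86 and 6.78, Cfb at 1.69 and 3.50, and Ubb-ps apart from the rest at -6.47 and 1.46.

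At day 3, 115 genes were higher and 104 lower in the knockout by the size rule, and at day 5, 137 were higher and 380 lower. Counting error alone put 70.5 genes past the rule at day 3 and 68.2 at day 5, and short RNA features with few reads made up 42 of the higher and 37 of the lower genes at day 3. Among the 11142 genes that also held at least 20 reads on average, a limit set after the data were seen, 75 were higher and 63 lower at day 3 and 95 were higher and 331 lower at day 5, against 0.7 genes from counting error at each day. Between the days, 39 genes were higher and 37 lower at both, where independent lists would share 1.34 and 3.35. The genotype differences at the 2 days, which share no library, had a Pearson r of 0.51 and a Spearman rho of 0.50 across genes, which are not independent replicates. The median of all genes was 0.13 at day 3 and 0.01 at day 5. Rescaling the libraries by their median ratio brought the day 3 median to -0.02 and turned the day 3 split into 70 higher and 156 lower. Rescaling to the same sum of RPKM gave 81 and 125, so the day 3 split depends on the scaling.

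Inflammatory NF-kB target genes as a group were higher in the knockout. Of the 24 measured, 6 passed the rule upward and 1 downward at day 3 and 7 upward and 1 downward at day 5, with a median of 0.49 at each day and a percentile of 100 among random lists matched on expression. Besides Saa3 and Marcksl1, Acod1, the itaconate enzyme, was higher by 1.39 and 2.18. Tnf was higher by 1.07 at day 3, close to the rule, and by 1.74 at day 5. Ccl22 was the member past the rule that went the other way. The inhibitors and other regulators of the pathway did not stand apart, with medians of 0.08 and 0.04 over 20 genes. The former median turned negative when libraries were rescaled by their median ratio. Of these genes only the co-activator Bcl3 passed the rule, by 1.18 at day 5. The list of 5 subunit genes had medians of -0.26 (percentile 0.3) at day 3 and -0.28 (percentile 4.08) at day 5. That list holds Nfkb1, the targeted gene, so its standing at day 3 is not independent of the design. Of the 33 antioxidant and redox genes, Sod2 alone passed the rule at either day. Their median was 0.22 at day 3 (percentile 79.5) and 0.21 at day 5 (percentile 98.3), and that standing at day 5 was lost with a pseudocount of 5 RPKM (percentile 97.49) and with no filter on low values (percentile 96.5). Interferon-stimulated genes had a median of 0.32 over 43 genes at day 5 (percentile 100), with 3 past the rule. These were the guanylate-binding genes Gbp2 and Gbp3, higher by 1.24 and 1.11, and Iigp1, higher by 1.09. Gbp2 and Gbp3 lie among the neighbours of Nfkb1 taken up under the other observations. At day 3 the interferon-stimulated genes did not stand apart (0.13, percentile 15.6), and that median turned negative under the median ratio rescaling.

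Genes of growth and energy use were also higher in the knockout than matched genes, mostly by amounts under the size rule. The 45 proliferation genes had medians of 0.53 at day 3 and 0.45 at day 5, both at percentile 100, with 41 and 43 members above 0 and 0 past the rule. The 20 glycolysis genes had medians of 0.52 and 0.64, both at percentile 100, and 5 of them passed the rule at day 5. Among these the triose isomerase Tpi1 was higher by 1.32, the phosphofructokinase Pfkl by 1.22, the lactate exporter Slc16a3 by 1.22 and the glucose transporter Slc2a1 by 1.19. At day 3 Pdk1 alone passed, at 1.02, and fell short of the rule under either rescaling (0.87 and 0.94). The 30 oxidative phosphorylation genes were above 0 at both days, with medians of 0.36 and 0.28 (percentile 99.7 at both), and cytochrome c, Cycs, passed the rule at day 3 with 1.14. The 85 ribosomal protein genes had a median of 0.30 at day 3 (percentile 99.9) and of 0.07 at day 5 (percentile 62.7). These medians kept their sign under both rescalings.

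Markers of dendritic cells and of class II antigen presentation were lower in the knockout. All 14 class II genes lay below 0 at day 5, with a median of -1.19 and 10 past the rule, and the median at day 3 was -0.85 with 3 past the rule (percentile 0 at both days). The class II chain gene H2-Aa stood at 1187 RPKM in wild type and 357 RPKM in the knockout at day 5, a difference of -1.73, and H2-Ob and H2-Eb1 differed by -1.52 and -1.42. Conventional dendritic cell markers had a median of -0.11 at day 3 (percentile 0.01) and of -0.68 at day 5 (percentile 0), with 11 of 31 past the rule downward at day 5. The largest were genes of the cross-presenting subset, Xcr1 at -2.08, Clec9a at -1.80 and Tlr3 at -1.78, with Clec10a at -1.59. Plasmacytoid dendritic cell markers had medians of -0.31 and -0.68 (percentile 0 at both days), and 9 of 24 passed the rule downward at day 5, among them Ccr9 at -1.52 and Siglech at -1.41.

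Markers of several other marrow lineages were lower in the knockout at day 5. The 27 late neutrophil granule and maturity markers were all below 0, with a median of -1.98 and 20 past the rule, led by Olfm4 at -3.35, Retnlg at -2.75, and Ly6g and Ltf at -2.50. At day 3 their median was -0.48, and Stfa2 and Olfm4 passed the rule. Primary granule and progenitor markers had medians of 0.02 at day 3 (percentile 5.25) and -0.49 at day 5 (percentile 0), with 5 of 15 past the rule, among them Fcnb at -2.001 and Cebpe at -1.52 at day 5. Mast cell, basophil and eosinophil markers had a median of -1.08 at day 5, with 11 of 20 past the rule, among them the basophil proteases Prss34 at -2.69 and Mcpt8 at -2.39, against -0.02 at day 3 (percentile 2.68). Megakaryocyte and platelet markers had a median of -1.005 at day 5 with 10 of 19 past the rule, such as Gp5 and Gp6 at -1.32 each, and of 0.04 at day 3 (percentile 7.75). The small day 3 medians of the primary granule and megakaryocyte lists turned negative under both rescalings.

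The medians of the lymphoid, red cell and stromal lists were also below those of random lists at day 5. The members past the rule downward were 3 of 16 T and NK cell markers, 4 of 22 B cell markers, 2 of 14 erythroid markers and 2 of 9 stromal and endothelial markers. T and NK cell markers had medians of -0.63 and -0.56 (percentile 0 at both days), with Cd3g, Cd3e at -1.51, Cd8b1 at -1.47 and Thy1 at -1.41 leading at day 3, each on 126 reads or fewer. B cell markers had medians of -0.03 (percentile 1) and -0.49 (percentile 0). At day 3 the receptor Cr2 was lower by -1.49 and Fcmr by -1.18, while Rag1, a recombinase of precursor cells, was higher by 1.06, and at day 5 Dntt, also a gene of precursors, was higher by 1.25. Rag1 stayed under the rule after either rescaling. Erythroid markers had medians of -0.12 (percentile 0.9) and -0.61 (percentile 0.01), with the globins Hba-a1 and Hbb-b1 at -2.32 and -2.21 at day 3, and the day 5 median of the list stayed within the range of random lists with no filter on low values (-0.07, percentile 4.23). Stromal and endothelial markers had medians of -0.13 (percentile 6.33) and -0.56 (percentile 0.43). The 40 monocyte and macrophage markers did not stand apart at day 3 (0.09, negative after the median ratio rescaling, percentile 5.24) or day 5 (0.16, percentile 95.1). Of these markers 6 were higher and 0 lower by the rule at day 3, and 6 were higher and 4 lower at day 5. Marco, Clec4e, Arg1 at 1.36 and Nr4a1 at 1.30 were among the higher ones at day 3. At day 5 Marco at 2.95 and Clec4e at 2.34 were higher, and Chil3 at -1.90 and Gpnmb at -1.41 were lower.

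**Figure D3:**
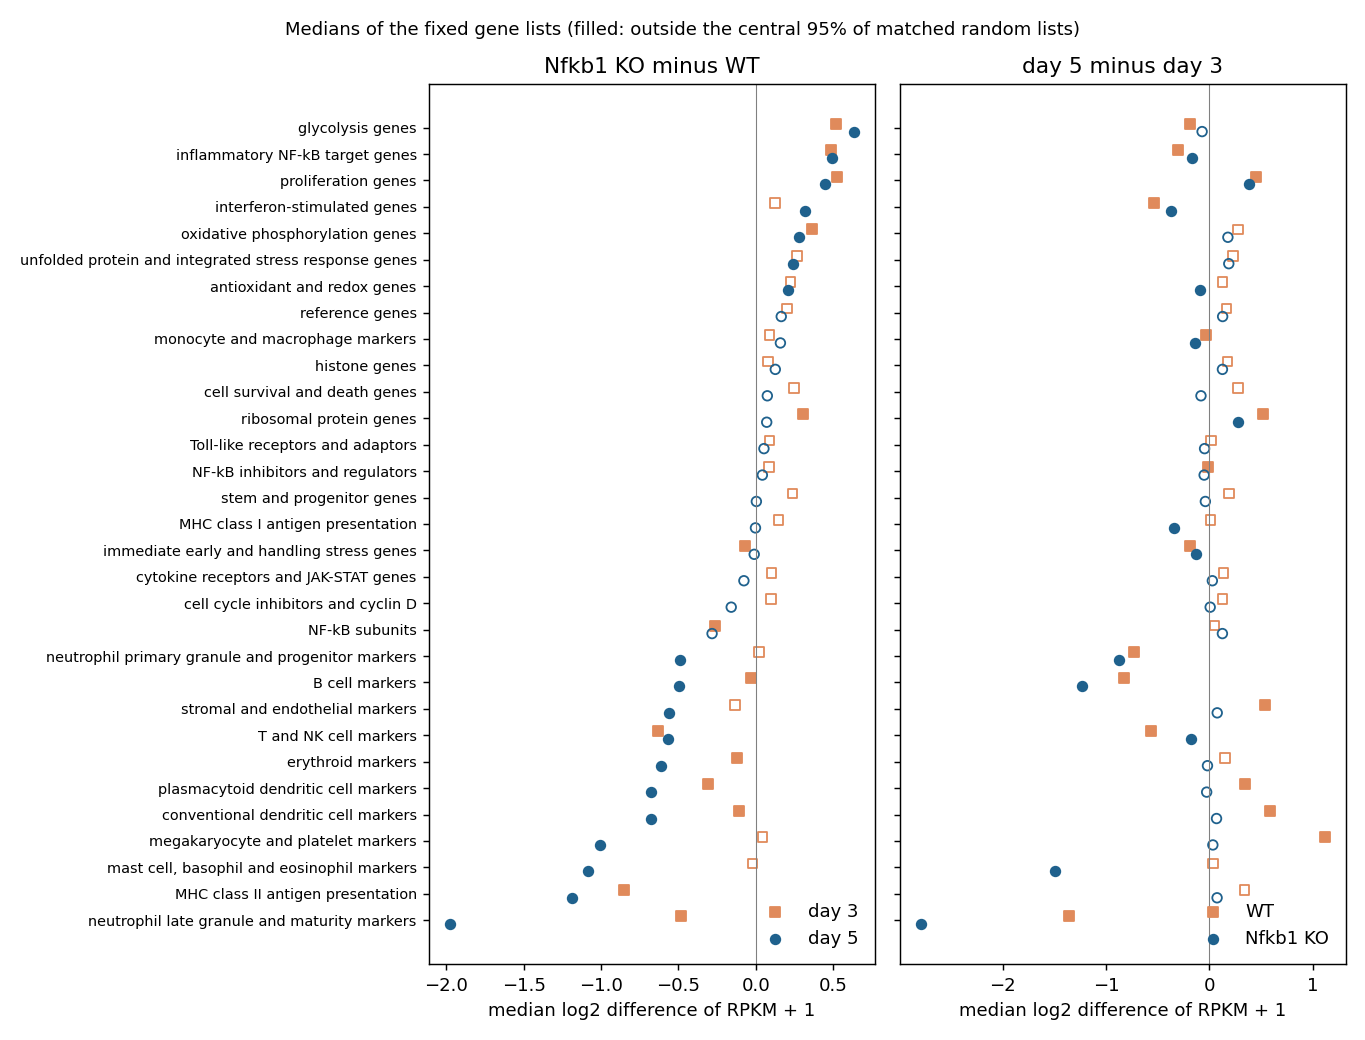
Median log2 difference of RPKM + 1 over the measured members of each gene list, for the knockout against wild type at day 3 and day 5 (left) and for day 5 against day 3 in each genotype (right); filled symbols lie outside the central 95% of matched random lists. Late neutrophil markers lie at -1.98 in the knockout against wild type at day 5, and megakaryocyte markers at 1.12 in wild type and 0.03 in the knockout between the days.

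At day 5 against day 3, 212 genes were higher and 242 lower in wild type, and 70 were higher and 355 lower in the knockout. With at least 20 reads on average these counts were 176 and 184 in wild type and 30 and 317 in the knockout. The wild-type split became 145 higher and 346 lower when libraries were rescaled by their median ratio, since the median of all genes in that comparison, 0.16, then moved to 0.01. Conventional dendritic cell markers had a median of 0.58 in wild type (percentile 100) with 8 of 31 past the rule, among them Xcr1 at 1.93, Itgae at 1.70, Clec9a at 1.68 and the integrin Itgax at 1.54, and of 0.07 in the knockout (percentile 69.3). Plasmacytoid markers had medians of 0.34 (percentile 99.5) and, positive when rescaled to the same sum of RPKM, -0.03 (percentile 14.5), the former ending within the range of random lists at a mean of at least 5 RPKM (percentile 95.7). Megakaryocyte markers had a median of 1.12 in wild type with 11 of 19 past the rule, among them Ppbp at 1.85 and Gp5 at 1.84, and of 0.03 in the knockout, where Nrgn alone passed. Flt3 was higher at day 5 by 1.47 in wild type, and differed by 0.79 in the knockout.

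Neutrophil markers were lower at day 5 in both genotypes. Late neutrophil markers had medians of -1.36 in wild type and -2.79 in the knockout (percentile 0 in each), with 26 and 27 of 27 past the rule. Primary granule markers had medians of -0.73 and -0.88 (percentile 0 in each), with 4 and 7 of 15 past it. S100a9, a calcium-binding protein of neutrophils, chosen after its values were seen because it had the highest RPKM in 3 of the 4 libraries, went from 13630 to 5325 RPKM in wild type and from 9254 to 1187 RPKM in the knockout. B cell markers had medians of -0.83 and -1.23 (percentile 0 for each). Interferon-stimulated genes had medians of -0.54 and -0.37 (percentile 0 for each), with the antiviral gene Rsad2 lower by -1.56 and -1.47. Mast cell, basophil and eosinophil markers had a median of 0.04 in wild type (percentile 6.53, negative after the median ratio rescaling) and -1.49 in the knockout (percentile 0). Of the genes lower at day 5 in both genotypes, the beta globin Hbb-b1 led, at -4.44 in wild type and -3.71 in the knockout, with Hbb-bs at the same values. Next came Slfn4 (-3.53 and -4.09), Slfn1 (-2.41 and -2.58), Cstdc4 (-2.23 and -3.28), the protease gene Asprv1 (-2.19 and -3.37), the alpha globins Hba-a1 (-3.56 and -1.90) and Hba-a2 (-3.39 and -1.90), H2-Q10 (-1.78 and -2.10) and Mmp25 (-1.77 and -2.52). Hba-a1 and Hba-a2 held the same reads in 3 of the 4 libraries (148, 52 and 25), so they cannot be counted as separate observations either. Higher in both genotypes were Nrgn (2.66 and 1.46), the serotonin transporter Slc6a4 (2.60 and 1.39), the collagens Col1a1 (1.27 and 1.27) and Col1a2 (1.79 and 1.25), Syt13 (1.88 and 1.26), Ctla2b (2.59 and 1.22), Ctla2a (2.77 and 1.19) and Ctnnd2 (1.30 and 1.18), beside Mir3112 and Mir7657 on 20 reads or fewer in any library. Over both genotypes 18 genes were higher and 143 lower at day 5, where independent lists would share 1.26 and 7.29, with a Pearson r of 0.53 and a Spearman rho of 0.42 across genes. Proliferation genes had medians of 0.45 and 0.38 and ribosomal protein genes of 0.52 and 0.28 (percentile 100 for each).

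The genotype difference moved between the days mostly downward, with 310 genes dropping by at least 1 and 118 rising, or 240 and 38 among genes with at least 20 reads on average. Short RNA features made up 75 of the rises and 69 of the drops. Late neutrophil markers dropped by a median of 1.43, with 19 of 27 past the rule, and the medians were -1.06 for megakaryocyte markers, -1.06 for mast cell, basophil and eosinophil markers and -0.53 for conventional dendritic cell markers (percentile 0 for each). Inflammatory NF-kB target genes had a median of 0.08 (percentile 99.8), which lost its standing with no filter on low values (-0.01, percentile 80.6). The largest rise was that of Ubb-ps at 7.93, a copy of the ubiquitin gene Ubb, followed by Mir7077, Mir7052, Mir6983 and Mir7658, each on 12 reads or fewer in any library. The largest drops were those of the histone gene H2ac11 at -3.44 (67 reads in wild type at day 5 and 6 or fewer elsewhere) and of Mir1902, Snord1a, Mir682 and Mir7019, each on 23 reads or fewer. No test of this change was possible, because 4 libraries leave no residual degree of freedom for it.

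An additive limma fit of genotype and day over the 4 libraries, which leaves 1 residual degree of freedom and takes any change of the genotype difference as error, gave 0 genes for genotype at a Benjamini-Hochberg adjusted p under 0.05, with 2278 genes at an unadjusted p under 0.05. The same fit gave 19 genes with an intensity trend, 4 with robust limma and, in settings added after the data were seen, 151 among genes with at least 20 reads on average and 716 with voom on the recovered reads. The lowest adjusted p in the limma fit was 0.0502, reached by Saa3 (5.82 ± 0.43 SE), Gimap3 (-2.06 ± 0.15 SE), Fcer2a and Mir7670. Sod2 had a difference of 1.37 ± 0.15 (SE) and an adjusted p of 0.0685 in limma, against 0.0467 with an intensity trend and 0.00282 with voom, and over the other settings limma gave it adjusted p values from 0.0239 to 0.252. For day the fit gave 136 genes by limma with Benjamini-Hochberg adjustment, 16 higher and 120 lower at day 5, led by Slfn4 (-3.81 ± 0.19 SE, adjusted p 0.00761) and Hbb-b1 (-4.08 ± 0.21 SE, adjusted p 0.00761). The count for day depended on the setting, with 0 genes after rescaling to the same sum of RPKM and with no filter on low values. On simulated libraries with no day effect and an assumed spread the same fit called 46 genes for day, so calls of this fit include false ones. The labels do not say whether libraries of one genotype came from one mouse or culture, so these p-values would not cover the spread between mice.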

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

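The test on Ubb-ps was chosen only after its values were seen. The plan was to look for opposite directions among named genes and list members, but all tested genes were searched, which added Snord37. In 7 genes the knockout library lay past the size rule on one side of wild type at day 3 and on the other side at day 5, and in each the difference was not tested. The change of the genotype difference between the days was 7.93 for Ubb-ps, 3.53 for Mir7077 and 2.41 for Mir6983, and -3.10 for Mir1902, -3.05 for Snord1a, -2.83 for Mir682 and -2.63 for Snord37. Apart from Ubb-ps these are short RNA features, and each held 18 reads or fewer in any library.

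Ubb-ps held 1685 reads in the wild-type library at day 3 against 9 in the knockout at day 3, 11 in wild type at day 5 and 48 in the knockout at day 5. A candidate explanation is that reads of Ubb, a gene of near-identical sequence, were placed on Ubb-ps in that library. Ubb alone had a ratio of knockout to wild type of 1.15 (1.10 to 1.20) at day 3 and 0.796 (0.765 to 0.828) at day 5. With the reads of both genes summed, the ratio was 0.803 (0.772 to 0.835) at day 3 and 0.803 (0.772 to 0.836) at day 5, so the summed reads moved alike where those of Ubb alone did not. In the same library Hba-a1 and Hba-a2 held 763 and 678 reads, and Hbb-b1 and Hbb-bs held 1950 and 1944. Within each of these globin pairs the reads were equal in every other library. Whether reads of near-identical copies were placed differently in the wild-type library at day 3 was not tested. Expression of Ubb-ps itself in one culture stays open, and a biological explanation was not tested.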

How the results depend on the processing

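The settings with at least 20 recovered reads on average and with voom were chosen only after the data were seen, and the cause of the changes was not tested except where a filter leaves fewer genes. No paired analysis was possible because the groups share only 1 replicate number; the additive limma fit compares the genotypes within each day but pairs no cultures. Of 155 list medians over the settings, 1030 values kept their standing, 20 lost and 29 gained it, and 1 reversed; of the values of named genes 2338 kept the size rule and 190 fell short of it, 162 of these with a pseudocount of 5 RPKM. Rescaling turned the sign of 29 list medians by the median ratio and of 22 by the same sum of RPKM, none of them from a list standing apart. Among lists standing apart, the sign turned for 1 median with a pseudocount of 0.1 RPKM, 2 with no filter on low values and 3 with a mean of at least 5 RPKM. Reads limit the counts, as genes with few reads pass the size rule by counting error.

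With a pseudocount of 0.1 RPKM, 228 genes were higher and 221 lower in the knockout at day 3, 225 and 648 at day 5, and 67 and 95 at both days. Between the days 418 were higher and 386 lower in wild type, 152 higher in the knockout and 47 higher in both genotypes, and the genes lower at day 5 in both genotypes numbered 224. The genotype difference rose in 207, the genes whose genotype difference dropped from day 3 to day 5 numbered 610, and limma called 4 genes for day. With a pseudocount of 5 RPKM the counts were 27 higher and 20 lower at day 3, 54 and 106 at day 5, 17 and 5 at both days, 58 and 78 between the days in wild type, 9 and 151 in the knockout, and 1 and 57 in both genotypes. The difference then rose in 30 and dropped in 84 genes, and limma called 3 genes for day.

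With a mean of at least 5 RPKM, which leaves fewer genes, 70 were higher and 40 lower at day 3, 90 and 228 at day 5, and 20 lower at both days. Between the days 106 were higher and 154 lower in wild type, 28 higher in the knockout and 10 higher in both genotypes, the difference rose in 39 and dropped in 170 genes, and limma called 20 genes for genotype. The median of T and NK cell markers between the days in wild type went from -0.56 (percentile 0) to 0.21 (percentile 63.4) there, with 4 of the 16 members left. Their median change of the genotype difference went from 0.21 (percentile 99.9) to -0.48 (percentile 2.21) there, and to -0.17 (percentile 39.7) with a pseudocount of 0.1 RPKM.

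When libraries were rescaled by their median ratio, 70 genes were higher at day 3, 25 were higher and 61 lower at both days, and limma called 286 genes for day. When rescaled to the same sum of RPKM, and likewise with no filter on low values, limma called 0 genes for day at an adjusted p under 0.05, with 2590 and 3381 genes at an unadjusted p under 0.05, against 710 adjusted calls with voom. With at least 20 recovered reads on average 75 genes were higher and 63 lower at day 3, 30 were higher at day 5 in the knockout, the difference rose in 38, and limma called 151 genes for genotype and 368 for day. For genotype limma called 19 genes with an intensity trend, 4 with robust limma and 716 with voom.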

Other observations

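The tests on the late neutrophil genes and on the neighbours of Nfkb1 were chosen only after those results were seen, while the test on Gapdh was fixed before its result, though the interval, the rule for reading it against -0.3 and the 4 genes set beside it were added after its value was seen. Several gene groups not yet described held smaller differences. Of 17 genes of the unfolded protein and integrated stress responses, 3 passed the size rule upward in the knockout at day 5, the asparagine synthetase gene Asns at 1.48 and the serine pathway genes Shmt2 at 1.25 and Phgdh at 1.12, with a list median of 0.24 (percentile 98) against 0.26 at day 3 (percentile 87.7). Among cytokine receptor and JAK-STAT genes the feedback inhibitor Socs3 was higher by 1.42 and the kinase Pim1 by 1.16 at day 5, while the receptor Csf3r of granulocytes was lower by -1.06, and the medians were 0.10 (percentile 16.6) and -0.08 (percentile 7.74). Of 22 Toll-like receptor genes and adaptors, Tlr2 was higher by 1.08 at day 3, though under the rule after either rescaling, and Tlr11 at -2.18, Tlr3 at -1.78, Tlr12 at -1.19 and Tlr6 at -1.06 were lower at day 5, with medians of 0.09 (percentile 18.4) and 0.05 (percentile 64.2). Of 28 stem and progenitor genes, 3 passed the rule upward at day 3, among them Egfl7 at 1.12. At day 5 Egfl7 was higher by 1.38 and Gata2 was lower by -1.16. The medians of that list were 0.24 at day 3 (percentile 94.5) and 0.00 at day 5 (percentile 45.1).

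Class I presentation genes had medians of 0.15 (percentile 35.4) and -0.00 (percentile 24.8) between the genotypes and of -0.34 (percentile 0.01) between the days in the knockout, where H2-Q6 was lower by -1.92. Cell survival and death genes had medians of 0.25 (percentile 88.5) at day 3 and 0.07 (percentile 68.1) at day 5, and cell cycle inhibitors and D cyclins of 0.10 (percentile 18.9) and -0.16 (percentile 3.34). Immediate early and handling stress genes had medians of -0.07 (percentile 0.11) and -0.01 (percentile 32.7), with 0 members past the rule between genotypes, and histone genes of 0.08 (percentile 42.7) and 0.13 (percentile 88.4). Of the sex-linked genes, Xist stood at 43.1, 36.6, 45.1 and 50.4 RPKM in wild type and knockout at day 3 and then at day 5, and the Y-linked genes listed stood at 0.0735 RPKM or less in each library. Reference genes had medians of 0.20 (percentile 61.9) and 0.16 (percentile 85.5), and Pgk1, also a glycolysis gene, was the member past the rule, at 1.02 at day 5, and ended under it after the median ratio rescaling. The day 3 medians of the class I, cytokine receptor, Toll-like receptor, cell cycle and histone lists turned negative under that rescaling, as did the day 5 median of the stem cell list, and rescaling to the same sum of RPKM turned the signs of the day 5 medians of the class I and immediate early lists. Slc15a2, chosen after its values were seen, held 152 and 99 reads in wild type and 5 and 4 in the knockout, a ratio of 0.0309 (0.00991 to 0.0738) at day 3 and 0.0423 (0.0113 to 0.112) at day 5.

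The lower late neutrophil genes of the knockout at day 5 were set against explanations other than the genotype. If one growing population had diluted all other cells alike, the lineage lists would have moved together, but the late neutrophil median lay 1.30 below that of conventional dendritic cells (difference -1.30, 95% bootstrap interval over genes -1.65 to -0.46). That prediction holds only if the growing cells carry none of the listed markers, which was not tested. The pseudocount also shrinks the differences of low genes, so unequal medians cannot decide against dilution. If the knockout culture had been further along the same time course, megakaryocyte genes, which were higher at day 5 in wild type, would have been as high in the knockout, but their median was -1.005 (-1.27 to -0.80). That prediction takes these genes to stay high after day 5, and wild type was not sampled later. The value therefore cannot decide against a knockout culture past the wild-type state of day 5. A difference in scaling or depth is argued against by the settings tried, over which the late neutrophil median ran from -2.02 to -1.54. Dilution by a growing population that carries some of the markers and a knockout culture past the wild-type state of day 5 stay open. An effect of the genotype, a different mix of cells in the marrow at the start and a difference between single cultures also stay open, because each genotype has 1 library per day.

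Gapdh, a glycolysis gene used as a reference in many assays, stood at 1.08, 0.775, 1.27 and 1.63 RPKM in wild type and knockout at day 3 and then at day 5, while Actb stood at 2380, 2339, 2397 and 2071 RPKM. A candidate explanation is that reads which also match pseudogene copies were not counted for the parent gene, since 90.4% of the 50-base windows of its transcript occurred unchanged in transcripts of other genes, against a median of 48.8% for ribosomal protein genes. The explanation called for a Spearman rho of -0.3 or below between shared share and RPKM across 82 ribosomal protein genes, but the rho was 0.18, with a 95% bootstrap interval over genes of -0.08 to 0.42 that reaches below 0 but not to -0.3. The set includes little-shared genes of low value, such as Rpl10l (7.60% shared, 0.0621 RPKM), Rpl3l (0%, 0.294 RPKM) and Rpl39l (0%, 0.358 RPKM). Such genes pull the rho upward, although Rpl29 (66.2%, 4.89 RPKM) goes the other way, so the rho cannot decide. The 4 ribosomal protein genes that share at least as much as Gapdh had means of 236 RPKM or more. The values of these 4 genes argue against a loss of every shared read, for those genes. The share does not count how many copies a window matches, so they cannot decide the question for Gapdh. What underlies the low value of Gapdh stays open, and no biological explanation was tested.

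A further hypothesis is that a segment around Nfkb1 from another mouse strain came with the knockout allele and might underlie part of the differences shared by both days, among them that of Alpk1, a neighbour of Nfkb1. Of the 100 nearest genes with at least 20 reads on average, 11 differed by at least 0.5 in the same direction at both days, against a median of 6 in 8782 overlapping windows elsewhere. That count lay at percentile 94.2, short of the upper limit set for the test, so the hypothesis was neither borne out nor excluded. A wider span had been looked at before, and the limits were set after those values were seen. Besides Alpk1 the 11 genes were Elovl6, Gar1, Bank1, Eif4e, Gbp5, Gbp3, Gbp2, Mcoln2, Adgrl4 and Ifi44, named because the test counted them, and the order of genes came from the GRCm38.p6 assembly.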
